A study of Homo sapiens with 2 samples.

How the data were processed

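RNA was sequenced from U2OS cells, an established human osteosarcoma line, that grew asynchronously and received 0.3 µM aphidicolin for 18 h. Aphidicolin inhibits the replicative DNA polymerases. Per the labels' protocols, polyadenylated RNA was selected with oligo(dT) beads, primed with random hexamers and sequenced as DNA nanoballs. The 2 libraries are replicates of 1 group. The labels do not say whether they came from separate cultures, so the spread between them may be technical. No untreated library was analysed here, and no effect of the treatment was tested.

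The deposited values are RPKM, reads scaled by exonic length and library total, per the file headers, in 1 table with a column per library. Per the submitters' processing notes, Trim Galore, HISAT2 and featureCounts were used, with the builds hg38 and GRCh38.p13. Tool versions, the gene annotation, the use of strand and any filter on genes are not given in the sources used here.

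The table had 18277 rows and 18141 distinct symbols. A set of 58 symbols had more than 1 row, and for 57 of them the rows held every combination of the values of both columns, so their 194 rows were left out. Of the 18083 remaining symbols, 334 shared both values with another symbol. Genome-wide counts took such values once, which left 17912 entries. The table held no value at 0, and genes that are not in it are called not listed.

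The design fixed before the data were examined assumed counts and set 1 CPM (reads scaled by library total alone) in both libraries as the level that counts as expressed. Because the files hold RPKM, the level became at least 1 RPKM in both libraries. That level was chosen after the unit was known. The 1 CPM level of the design was computed as well, from recovered reads. Recovering reads from the RPKM was decided after the data were seen, so these values count as added later, and they stand beside the main ones where they reverse a difference or move a count by over 1.5 times.

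Reads were recovered from the RPKM as follows. For 100% of genes the ratio of both columns was a ratio of whole numbers within a relative tolerance of 2e-13. The 1019 genes with equal reads set the ratio of the library totals, and the totals were 13227805 reads for replicate 1 and 13020149 for replicate 2. Reads per gene were known up to a whole factor, which was set from the exonic length in GENCODE release 29. The resulting length was within 10% of GENCODE's for 91.0% of matched genes and equal to it for 43.9%. The factor was set to bring each length near GENCODE's, so the 91.0% is partly built in and is no independent check. Recovered reads of the listed entries came to 98.1% of the total in each library. A gene with 2 kb of exon at 1 RPKM thus held 26.5 reads in replicate 1 and 26.0 in replicate 2. Counting error at that depth is large, and it is the only error these numbers cover. On data simulated for 17444 genes, both totals were recovered exactly.

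Symbols were matched to GENCODE release 29 on GRCh38 for 96.4% of genes, and 583 of the 659 unmatched symbols began with LOC. Span is the distance from gene start to gene end, and coordinates are 1-based. Large genes span at least 300 kb. The share of exonic bases shared with another gene was counted on either strand.

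Levels are means of the 2 libraries with the SD, and log values are log2(RPKM + 1). The median of each gene list fixed beforehand was placed among the medians of 10000 random lists of the same size. For common fragile site genes, random lists of the same spans were drawn as well. These percentiles describe these libraries, and genes are not independent replicates. Span was correlated with level across genes using 100000 permutations, 2-sided, with Benjamini-Hochberg adjustment over 3 correlations.

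The libraries were compared with a 2-sided exact binomial test on recovered reads, with trimmed mean of M values scaling (factor 0.9956 for replicate 2) and Benjamini-Hochberg adjustment at 0.05. This test compares these libraries and no conditions. On simulated data for 200 genes changed 2-fold, 99.0% were called, and 2.9% of 204 calls were unchanged genes. Those simulated libraries held counting error alone, and the changed genes were drawn from genes with many reads. These rates therefore need not hold for the real libraries. A common coefficient of variation beyond counting was fitted to the recovered reads, and 3.08% was found where 3% was simulated.

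The rule for named genes took the 20 highest genes, the fragile site genes past the level and the longest 3 below it. It also took the 3 highest of every other list, the 10 longest expressed genes, up to 10 genes per direction that differed between libraries, and a list of genes of the line. Some genes that the rule took are not reported here. Ranks used RPKM in place of the planned CPM. Alternatives covered the level, the scaling, the background, the pseudocount, the span limit and each library alone. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.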

Results

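Polyadenylated RNA was measured in 2 libraries of U2OS osteosarcoma cells held in 0.3 µM aphidicolin for 18 h. The series maps sites of DNA synthesis in mitosis and common fragile sites, loci that break when replication is slowed. The RPKM rest on 13227805 reads in replicate 1 and 13020149 in replicate 2. Values below are means ± SD with n = 2 unless a replicate is named.

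TMSB10, which encodes an actin-binding thymosin, was highest at 2314 ± 45.5 RPKM, followed by the glycolytic enzyme gene GAPDH at 1943 ± 40.7 and the actin gene ACTB at 1885 ± 14.7. The ferritin light chain gene FTL stood at 1318 ± 27.1, the chaperone gene HSP90AB1 at 866 ± 10.4 and the tubulin gene TUBB at 733 ± 22.0. TIMP1, LGALS1, MT2A, PABPC1, RPS12, RPL8, PTMS, ACTG1, RPL19, HMGA1, EEF2, ENO1 and CALR were also among the 20 highest genes, from 723 RPKM for TIMP1 down to 439 RPKM for CALR. The metallothionein gene MT2A varied most among the genes just described, at 592 RPKM in replicate 1 and 713 RPKM in replicate 2. The 20 genes together took 3.5% of the reads in each library. In total 11944 of 17912 entries (66.7%) reached 1 RPKM in both libraries, 11367 of them protein-coding genes. Replicate 1 alone had 12142 and replicate 2 alone had 12129.

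Both libraries gave nearly the same levels. Among the genes called different, the largest log2 ratio in either direction belonged to EIF3C and its near-identical copy EIF3CL. EIF3C, a translation initiation factor gene, had 303 reads in replicate 1 and 143 in replicate 2, a log2 ratio of replicate 2 over replicate 1 of -1.05 ± 0.15 (counting SE). Its copy EIF3CL had 53 and 186 reads, a log2 ratio of 1.84 ± 0.22. Reads of these copies are uncertain because counting can split them. MTRNR2L2, annotated as a processed pseudogene, had 39 and 125 reads, a log2 ratio of 1.71 ± 0.26. THOC3, HOXB-AS3, DNAJC30, RASA3, SORD, CSNK2B, POLR2J and ADAMTSL1 were the next highest in replicate 2, with log2 ratios from 0.81 for THOC3 to 0.33 for ADAMTSL1. PRR7, KLHL13, IFI6, VPS51, HMGN5, ESF1, MARCHF9, RNPEPL1 and PGP were the next highest in replicate 1, with log2 ratios from -0.62 for PRR7 to -0.31 for PGP. Across 11943 expressed genes Pearson's r was 0.997 and Spearman's rho 0.996. The exact binomial test with Benjamini-Hochberg adjustment called 199 genes (1.7%), 119 higher in replicate 2 and 80 higher in replicate 1, and 7 of them differed by at least 1.5-fold. Chi-square per degree of freedom was 1.79, so the libraries differed by more than counting error, the only error this value and the 199 calls cover. Duplicate reads from amplification, or separate preparations of 1 culture, would also give a value above 1. The coefficient of variation beyond counting was 2.70%.

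**Figure D1:**
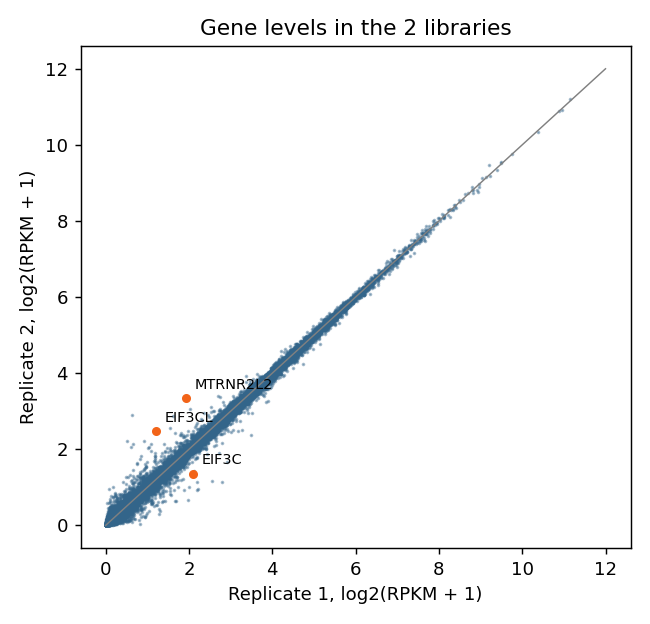
Each point is a listed gene, with log2(RPKM + 1) in replicate 1 on the x axis and in replicate 2 on the y axis; the line marks equal levels. Orange points name EIF3C, EIF3CL and MTRNR2L2, the genes farthest from the line among those that differed.

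How often large genes passed the level, compared with other genes, depended on the level and on the division by exonic length. At 1 RPKM, 399 of 788 large genes (50.6%) and 11440 of 16563 other genes (69.1%) were expressed, a difference of -18.4 percentage points. At 1 CPM, computed from recovered reads and not divided by exonic length, the shares were 79.8% and 79.5%, a difference of 0.3 percentage points, but more genes pass that level. At 4.3 CPM, the level passed by as many genes as 1 RPKM, the shares were 62.6% and 68.5%, a difference of -6.0 percentage points. Median CPM was 11.2 for large genes and 20.9 for other genes. Of the 10 longest expressed genes, the netrin-G ligand gene LRRC4C reached 12.4 ± 0.032 RPKM with a span of 1346 kb. The transcription factor gene RUNX1 reached 9.91 ± 0.066 with 1217 kb and TBC1D5 reached 9.90 ± 0.058 with 1288 kb. Spans are those of the annotated genes, and which part of them was transcribed was not measured. The longest expressed gene was CSMD1, on chromosome 8 from 2935353 to 4994972, at 1.39 ± 0.016 RPKM. NRXN3, RBMS3, KAZN, ZFPM2 and AUTS2 were also among the 10 longest expressed genes, between 1.02 RPKM for RBMS3 and 3.17 RPKM for AUTS2. The share at 1 RPKM was 67.5% under 50 kb, 73.5% from 50 to 100 kb, 71.0% from 100 to 300 kb, 55.7% from 300 to 500 kb, 44.5% from 500 to 1000 kb and 35.9% at 1000 kb and over. At 1 CPM the same classes gave 76.4%, 85.1%, 86.7%, 80.8%, 81.6% and 65.6%. Over annotated protein-coding genes, with those not listed taken as 0, the shares at 1 RPKM were 53.7%, 66.8%, 67.0%, 53.9%, 43.1% and 33.8%, and the difference between large and other genes was -8.9 percentage points. Median exonic length grew along them from 3740 to 11100 bases. Across 17351 genes Spearman's rho of span and log2(RPKM + 1) was -0.04, and it was -0.22 across the 3458 genes of at least 100 kb. The adjusted permutation p was 1e-05 for each, the smallest these permutations can give, and genes are not independent replicates. Exonic length divides the RPKM and grew with span, so part of a negative rho may be built in. The permutations do not test against that.

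**Figure D2:**
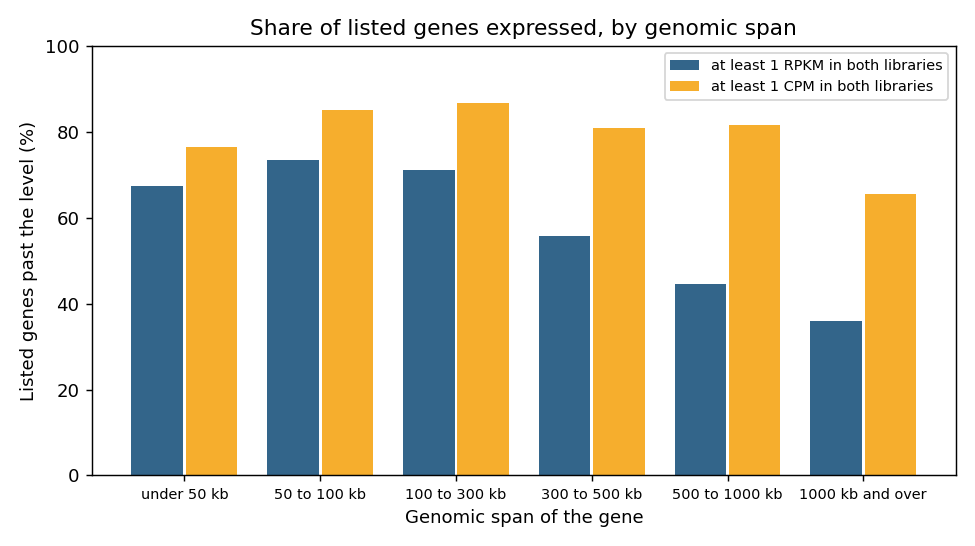
Bars give the percentage of listed genes that passed the level in both libraries, on the y axis, for 6 classes of genomic span on the x axis. Blue bars (1 RPKM) go from 67.5% in the shortest class to 35.9% in the longest, and yellow bars (1 CPM) from 76.4% to 65.6%.

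Genes at common fragile sites ranged from 0.0101 RPKM for DMD to 15.1 RPKM for TENM3, and 16 of the 35 listed members reached 1 RPKM in both libraries. The teneurin gene TENM3, on chromosome 4 from 182143987 to 182803024, was highest at 15.1 ± 0.17 RPKM. The adhesion gene NEGR1 (chromosome 1, 71395940 to 72282734) stood at 6.33 ± 0.059, the exocyst gene EXOC4 (chromosome 7, 133253073 to 134066589) at 5.89 ± 0.26 and the phosphatase gene PTPRG (chromosome 3, 61561569 to 62297613) at 5.78 ± 0.076. WWOX, the gene at FRA16D on chromosome 16 from 78099413 to 79212667, was at 3.43 ± 0.29 RPKM. FHIT, the gene at FRA3B on chromosome 3 from 59749310 to 61251459, had 20 reads in replicate 1 and 9 in replicate 2, or 0.147 ± 0.078 RPKM. CDH13 was at 5.04 ± 0.12 RPKM, SDK1 at 4.70 ± 0.29, LPP at 4.31 ± 0.063 and DIAPH2 at 3.97 ± 0.078. AUTS2, DPYD, RORA, IMMP2L and CSMD1 lay between 3.17 RPKM for AUTS2 and 1.39 RPKM for CSMD1. The longest members below 1 RPKM were CNTNAP2 at 0.700 ± 0.0045 over 2305 kb, the dystrophin gene DMD with 1 and 4 reads over 2242 kb, and DLG2 at 0.665 ± 0.083 over 2173 kb. At 1 CPM, 26 members passed, the other 10 being CNTNAP2, DLG2, NBEA, IL1RAPL1, FOXP1, LSAMP, DAB1, MAGI2, MACROD2 and PDE4D. CCSER1 was not listed.

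The median of the fragile site list was 0.665 RPKM (0.697 in replicate 1 and 0.636 in replicate 2). It lay at percentile 0.17 of random lists drawn from all genes, and at percentile 57.7 of random lists of the same spans. In CPM, not divided by length, these percentiles were 13.99 and 80.0, so the low place among all genes depended on the measure. At an equal number of transcripts, CPM is higher for genes with more exonic sequence. The change therefore does not show that the division made the low place. Random lists of the same spans had a median of 14 expressed genes, with 95% of lists between 9 and 20. The 16 expressed fragile site genes thus lay inside the range of those lists. The span classes drawn from hold the fragile site genes too. Of the other listed genes of 500 kb or more, 116 of 274 (42.3%) were expressed. Among the 35 listed fragile site genes, all of at least 500 kb, the share was 45.7%. Of the fixed list of other very large genes, 28 of 41 listed members were expressed. COL4A2 led them at 40.3 ± 2.1 RPKM, though its span of 207 kb is under the limit for large genes. EXT1 followed at 23.8 ± 0.78 and PARD3 at 19.9 ± 0.32. The shortest listed fragile site gene spans 588 kb, so the shares of these 2 lists are not matched on span.

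**Figure D3:**
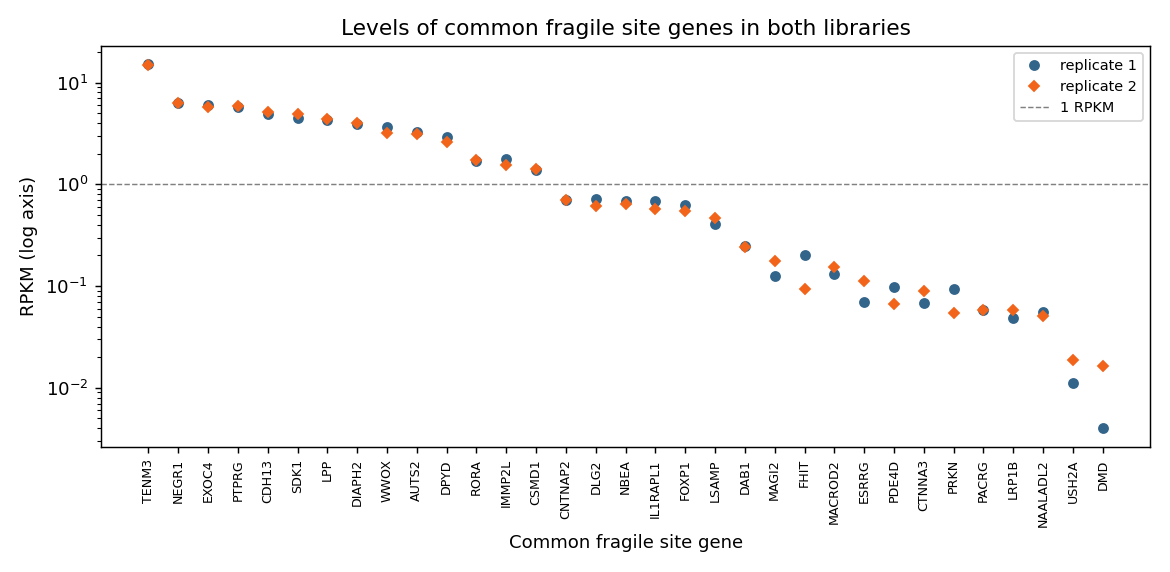
Points give the RPKM on a log axis of listed common fragile site genes on the x axis, ordered by mean level, in replicate 1 (circles) and replicate 2 (diamonds), and the dashed line marks 1 RPKM. TENM3 is highest at 15.1 RPKM and DMD lowest at 0.0101 RPKM.

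Most listed genes of replication and division were expressed in these cells, which were given an inhibitor of the replicative polymerases. The exceptions were NUSAP1 at 0.180 RPKM and RTEL1 at 0.236 RPKM, and SLX1A was not listed. All 31 listed replisome genes passed 1 RPKM, led by the sliding clamp gene PCNA at 216 ± 5.3 RPKM, the helicase gene MCM3 at 103 ± 1.3 and the flap nuclease gene FEN1 at 92.7 ± 1.3. POLA2 was left out because it had several rows. All 28 S phase genes passed, led by TK1 at 147 ± 3.4, TYMS at 78.4 ± 2.6 and ATAD2 at 75.3 ± 0.58, and 46.6% of the exonic bases of TYMS are shared with another gene. Of 33 genes of G2 and mitosis 32 passed, led by TOP2A at 171 ± 3.0, CCNB1 at 157 ± 4.0 and TPX2 at 152 ± 3.3. All 22 members of the fixed list for the ATR checkpoint passed, though that list is not limited to the ATR pathway. They were led by the histone variant gene H2AX at 146 ± 15.6, PRKDC at 52.8 ± 1.8 and CDC25B at 49.6 ± 2.4. Of 29 listed factors of mitotic DNA synthesis and fork rescue 28 passed, led by SMC2 at 35.7 ± 0.21, FANCI at 34.6 ± 1.2 and TOPBP1 at 32.5 ± 1.1. The list medians lay at percentiles from 98.9 for the fork rescue factors to 100 for the replisome, S phase and mitosis lists. With no untreated library, these are levels and not responses.

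Of a further fixed list of 25 genes, which holds regulators of cell cycle arrest and apoptosis, 24 were expressed, led by the cyclin gene CCNG1 at 80.5 ± 2.1 RPKM, the cell cycle inhibitor gene CDKN1A at 78.6 ± 0.47 and BAX at 39.1 ± 0.17. SPATA18 was below the level at 0.0153 RPKM. Among genes of the line, CCND1 was at 70.4 ± 0.70 RPKM, CDK4 at 43.7 ± 1.3, MYC at 26.4 ± 0.33, PPM1D at 20.97 ± 0.35, IGF1R at 18.8 ± 0.53 and RB1 at 16.7 ± 0.48. MTAP stood at 5.67 ± 0.24, MDM4 at 5.40 ± 0.31 and CDKN2B at 2.01 ± 0.18. CDKN2A, on chromosome 9 from 21967753 to 21995301, had 1 read in replicate 1 and 3 in replicate 2. Of 17 listed telomere maintenance genes 16 passed, led by ASF1B at 47.8 ± 0.81, DKC1 at 40.8 ± 0.96 and DAXX at 30.9 ± 0.28. TERT, TERC and TEN1 were not listed.

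Of the osteoblast and mesenchymal list, 21 of 25 listed members passed, led by SPARC at 280 ± 3.7 RPKM, VIM at 249 ± 0.23 and COL1A1 at 209 ± 0.88. Below the level were ACTA2 at 0.804 ± 0.48 RPKM, the osteocalcin gene BGLAP at 0.277 ± 0.059, COL1A2 at 0.0515 ± 0.044 and DCN at 0.0153 ± 0.013, and SP7, IBSP, POSTN and TWIST1 were not listed. Interferon response and nucleic acid sensing genes passed in 17 of 23 cases, among them IFI44 at 31.8 ± 1.2 and IFI6 at 30.2 ± 5.8. IFI6 was also among the genes that differed between the libraries. Secreted inflammatory factors passed in 13 of 17 cases, among them TGFB1 at 91.0 ± 1.9 and LIF at 23.1 ± 1.1. Replication-dependent histone genes, most of whose transcripts lack a poly(A) tail, passed in 11 of 14 listed cases with a median of 2 RPKM. Of the 22 members of that list, 8 were not listed in the data. H1-2 at 43.6 ± 2.0, H2BC12 at 26.5 ± 0.44 and H2BC21 at 5.67 ± 0.85 led the histone genes. All 44 ribosomal protein genes passed, from 38.3 to 564 RPKM, led by RPS12, RPL8 at 545 ± 26.1 and RPL19 at 464 ± 20.2. All 20 housekeeping genes passed, led by GAPDH, ACTB and HSP90AB1. None of the 15 mitochondrially encoded genes was listed.

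Markers of other cell types were mostly below 1 RPKM. Haematopoietic markers passed in 1 of 12 listed cases, CD3D at 1.11 ± 0.046 RPKM, with CD4 at 0.811 and CSF1R at 0.474. Hepatocyte markers passed in 1 of 10, SERPINA1 at 59.8 ± 1.6, with CYP2E1 at 0.475 and HPX at 0.315. Endothelial markers passed in 3 of 13, EGFL7 at 19.9 ± 0.94, SOX17 at 2.16 ± 0.23 and ERG at 2.03 ± 0.027. Epithelial markers passed in 5 of 17, led by MUC1 at 4.35 ± 0.64, EPCAM at 2.28 ± 0.21 and CLDN4 at 1.97 ± 0.24. Neuronal markers passed in 6 of 16, led by SNAP25 at 5.73 ± 0.31, SLC17A7 at 3.96 ± 0.34 and SYP at 3.56 ± 0.15. At 1 CPM haematopoietic markers passed in 3 of 12 cases, hepatocyte in 3 of 10, endothelial in 9 of 13, epithelial in 9 of 17 and neuronal in 8 of 16. Most listed endothelial and epithelial markers thus passed that level.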

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

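The 1 CPM level was fixed in the design, but computing it from reads recovered from RPKM was decided after seeing the data. Alternatives with 0.5 RPKM, 5 RPKM, annotated genes that are not listed taken as 0, levels in CPM and genes with little overlap were chosen after seeing the data. The number of expressed genes stayed within 1.5 times of the main count except at 5 RPKM (7660). The difference between large and other genes (-18.4 percentage points) reversed at 1 CPM (0.3), 0.5 CPM (2.4) and 10 reads (1.7); these settings do not divide by exonic length and are also passed by more genes. It was -6.4 at 5 CPM, -6.0 at the CPM level passed by as many genes as 1 RPKM, which was also chosen later, -10.7 at 1 TPM, -14.7 at 0.5 RPKM, -26.9 at 5 RPKM, -19.9 for protein-coding genes, -8.9 over annotated protein-coding genes, -26.0 with large set at 500 kb, -19.4 for genes with under 10% of exonic bases shared, and -18.9 to -18.8 without either replicate. Expressed fragile site genes (16) numbered 26 at 1 CPM, 31 at 0.5 CPM, 29 at 10 reads and 4 at 5 RPKM. The percentile of their median among all genes (0.17) was 9.03 over annotated protein-coding genes and 13.99 with levels in CPM; among genes of the same spans it stayed between 45.4 and 80.0. Of 220 list counts, 191 stayed within 1.5 times of the main count and 29 did not, 19 higher and 10 lower, and 24 of the 29 were in the 5 lists of markers of other cell types. At 5 RPKM the other very large genes numbered 11, the histones 4, the interferon list 11, the inflammatory list 7, and the haematopoietic, epithelial, endothelial and neuronal markers 0, 0, 1 and 1. At 5 CPM the histones numbered 4 and the haematopoietic markers 0. The haematopoietic, epithelial, endothelial and hepatocyte markers numbered 3, 9, 9 and 3 at 1 CPM, 6, 10, 11 and 3 at 0.5 CPM, 5, 10, 9 and 3 at 10 reads, and 4, 10, 9 and 3 at 1 TPM. Neuronal markers numbered 10 at 0.5 CPM, and at 0.5 RPKM the haematopoietic and endothelial markers numbered 2 and 7. The genes that differed between the libraries (199) numbered 108 at an adjusted p under 0.01 and 7 with a fold of 1.5 required, by construction of stricter limits. Apart from the stricter limits and the part of the length division weighed under the other observations, the cause was not tested. Leaving mitochondrial genes out of the total and a dispersion from a second package were not run, the first because no such gene is listed. Zeros in the table could not be included because it holds none. Depth limits genes of few reads, such as FHIT, DMD and CDKN2A.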

Other observations

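The tests of exonic length against ribosomal protein levels, of the median level in CPM and of the CPM level passed by as many genes as 1 RPKM, and the overlap test at 1 CPM, were chosen only after their results or inputs were seen, and every pattern below was first noticed in these data. Of 21 gene lists, the interferon list had a median log2 ratio of replicate 2 over replicate 1 of -0.06, at percentile 2.2 of random lists matched on level. The other very large genes had a median log2 ratio of 0.06, at percentile 98.6.

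Large genes passed 1 RPKM less often than other genes. The tables argue against overlap of exons as the cause: the difference was -19.4 percentage points among genes with under 10% of exonic bases shared. Among listed genes, division by exonic length did not account for the whole difference at a matched number of genes. The data hold no value at 0, and that comparison was not made over annotated genes. The division is therefore not excluded there as the whole cause. The bound set beforehand for this cause was met at 1 CPM, with a difference of 0.3 percentage points, but more genes pass that level, and the difference was -6.0 at the CPM level passed by as many genes as 1 RPKM. Among listed genes the division may account for the part between -18.4 and -6.0. CPM in turn favours genes with more exonic sequence, which large genes tend to have. That part may therefore also come from CPM itself. Which genes are listed also matters. With the division kept, the difference was -19.9 for listed protein-coding genes and -8.9 over annotated ones, those not listed taken as 0. The median log2(CPM + 1) of listed large genes lay -0.84 from that of other listed genes, against -1.31 for log2(RPKM + 1). No biological explanation was tested.

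Single genes of dividing cells lay near 0 while their lists did not. NUSAP1, a spindle gene, had 8 and 9 reads, and the helicase gene RTEL1 had 22 and 18. Both of these 2 genes share at least 50% of their exonic bases with another gene, against 1 of the 139 other members (Fisher's exact test, 2-sided, p = 0.000304). RTEL1 passes 1 CPM, at 1.66 and 1.38 CPM, so that NUSAP1 alone is below that level (p = 0.0213 by the same exact test). Over protein-coding genes, the median log2(RPKM + 1) of the 30 with at least 90% of exonic bases shared lay -2.31 from that of the 8281 with none shared. Reads lost where genes overlap are a candidate explanation for these low values, and RAD50, chosen after its value was seen, had 79.7% shared at 0.627 RPKM. SDHA, also chosen afterwards, was at 2.01 RPKM with none shared, and whether heavily overlapped genes are less transcribed was not tested.

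Ribosomal protein genes spread 14.7-fold in RPKM. Spearman's rho of level and number of processed pseudogenes was -0.12 over 44 genes (permutation p = 0.43) and -0.02 without the 2 genes with the most extreme numbers. Median levels were 167 RPKM for the 19 genes with 10 or more pseudogenes and 174 RPKM for the 25 others. Pearson's r was -0.27. The genes with the most pseudogenes, RPSA (73), RPL7 (61) and RPS3A (38), were at 67.3, 45.1 and 43.2 RPKM, against a list median of 171. The next, RPL7A (37) and RPL5 (34), were at 183 and 167 RPKM. Over so few genes these values do not tell whether reads were lost to pseudogenes. The rho with exonic length was -0.64 (adjusted permutation p = 6e-05). Length divides the RPKM, and shuffled reads gave a median rho of -0.67 by construction, so an exonic length that is longer than the main transcript cannot be told apart from that built-in relation.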
